A study of Mus musculus with 6 samples.

How the data were processed

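White adipose tissue RNA from 6 samples, 3 control and 3 YY1aKO, was measured on 1-colour Affymetrix arrays, 1 array per sample. Per the labels' protocols, total RNA was extracted with Trizol and turned into biotin-labelled cRNA. The deposited values are 1 intensity per probe set and array, made with RMA per the submitters' processing notes, which give no version or settings. RMA corrects the background, makes the distributions of the arrays alike and summarises the probes of each set, so a change shared by most genes would be removed from these values. RMA usually gives log2 values, but the deposited intensities run from 6.09 to 30322 and are on a linear scale. How they were returned to it is not stated. Their log2 was taken before any test. Very bright probe sets, such as those of Adipoq and Fabp4, lie near the top of this scale, where a scanner can compress differences.

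The table held 22690 probe sets, of which 64 were array controls and were left out. The platform annotation gave a single gene symbol for 20380 probe sets and several for 691, and 1555 further probe sets have no gene named in it. Of the single-symbol probe sets, 20351 were matched to the current reference gene table by Entrez ID, and 0 symbols were updated. Each of 12393 genes was represented by its probe set with the highest mean over the 6 arrays. The 60% of genes with the highest mean (7436, mean log2 intensity of at least 6.83, or 114 on the linear scale) were tested. Where a gene has several probe sets these can disagree. Of 2533 genes with several probe sets over the filter level, 441 were called by some but not all, and 2, Wdr26 and Msl1 (chosen after their values were seen), in both directions. The annotation names no genome build for the probe sets, so no coordinates are given.

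Groups were taken from the genotype label. limma 3.58.1 in R 4.3.3 was used (lmFit and eBayes, 1 prior variance), with Benjamini-Hochberg adjustment over all genes tested, a threshold of 0.05 and two-sided tests. Fold changes are YY1aKO minus control on the log2 scale. Because no label says that samples came from separate animals, the p-values measure the spread between samples. Genes below the filter are given with the adjusted p of the fit with no filter. Before the data were examined, 42 gene lists covering 944 genes were fixed, and 829 of these genes have a single-gene probe set. The 33 lists with at least 5 tested members were tested with camera against all other genes, with a preset inter-gene correlation of 0.01 and adjustment over the lists. With a correlation estimated per list, none of the calls held (adjusted p of 0.993 for every list with 6 arrays, and 0.859 or more without control 2). The estimates with 6 arrays ran from -0.04 for hypoxia to 0.96 for endothelial cells. This version of camera rests on the few residual degrees of freedom of the arrays. It made no call in any setting in which it was run. The estimates were 0.51 for cholesterol synthesis and 0.53 for interferon-induced genes, which passed with the preset 0.01. This version was not run on simulated data, so whether it can tell a list that moved from one that did not is not known. The count of members past the threshold is given over all genes tested and adjusted over the list alone.

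The text names genes from a rule fixed with the lists: a set of key genes with their values whether or not they pass, the 10 largest rises and 10 largest falls among genes that passed and lay outside the control range, up to 4 members past the threshold per list (or up to 2 with the smallest p where none passed), and the measured sex-linked genes and neighbours of Adipoq. Some list members of this rule that did not pass are not printed, but count among the named genes in the alternatives. Epididymal genes and genes named as chosen after their values were seen are exceptions. The scripts were tested on simulated data with 200 of 7436 genes changed. With 6 arrays, 61% of the genes changed 2-fold and 85% of those changed 4-fold were recovered, and 5.19% of calls were false. Without control 2 the same shares were 88%, 94% and 2.67%. The simulated noise was independent between genes and had the same spread on every array, unlike these data, where control 2 stands apart. These shares therefore check the scripts and are not the error rates of the real comparison.

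Alternatives set before the data were examined were the mean of all probe sets of a gene, every probe set on its own, leaving out probe sets with the suffix _s_at or _x_at, no filter or a stricter filter on dim genes, quantile normalization again, the same median on every array, an intensity trend with a robust prior, array weights, a replicate block, each replicate left out, other thresholds, an unequal-variance test, camera with an estimated correlation, and fry. Chosen after seeing the data were control 2 left out together with a fold threshold, control 2 left out together with 1 further array, the mean of the epididymis list as a covariate, an estimated correlation in other settings, and the list of YY1 partners without Yy1. Array weights and the covariate bear mainly on control 2, so they come near to leaving it out and are not separate checks. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No sample was left out of the main comparison.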

Results

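Gene expression was measured in white adipose tissue of 8-week-old mice of mixed C57BL6 and 129 background, after 4 days of cold exposure at 4 °C. Cold recruits thermogenesis, the burning of fuel for heat, in brown adipocytes and in the brown-like (beige) adipocytes of white fat. Control mice carried Yy1 alleles flanked by recombination sites. YY1aKO mice carried these alleles together with Cre recombinase under the Adiponectin promoter, which is active in adipocytes. YY1 is a zinc-finger transcription factor that can activate or repress its targets. There were 3 samples per group, each on its own 1-colour Affymetrix array, and the labels do not say whether each came from a separate animal. The number of arrays limits the precision of every value. The labels disagree on the depot, since the sample titles carry the prefix EWAT and the tissue field says visceral, while the series title and the sample descriptions say subcutaneous. The series title also places the deletion in brown fat, while the genotype field and the design text place it in adipose tissue through Adiponectin-Cre.

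The 6 arrays had similar distributions, with median intensities from 134 to 140. Control replicate 2 stood apart from the rest. Over the 7436 genes tested it correlated with the other arrays at 0.812 to 0.890 (Pearson, across genes, which are not independent replicates), while controls 1 and 3 correlated at 0.977 and the YY1aKO arrays with each other at 0.988 to 0.990. It carried high levels of genes expressed in the epididymis, the sperm-storing duct of the male reproductive tract. Lcn8, a lipocalin secreted by the epididymis, read 28166 in control 2 against 50.6 in control 1 and 49.2 in control 3, and its highest level in YY1aKO was 59.9. Gpx5, an epididymal glutathione peroxidase, read 21047 in control 2, 639 in control 3, 39.0 in control 1 and at most 41.5 in YY1aKO. Values for each group of genes are therefore also given without control 2, a comparison of 2 control with 3 YY1aKO arrays.

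The targeted gene separated the groups on every array. Yy1 read 1785, 1846 and 1596 in controls 1 to 3 and 373, 323 and 315 in YY1aKO 1 to 3, a log2 fold change of -2.37 ± 0.11 (SE, n = 3 per group), or 5.18-fold lower, with a limma adjusted p of 0.0021. Of its other probe sets, 1 fell by 1.21 and 1 by 1.03 on the log2 scale. The last read 38.5 to 43.1 on all arrays, with a log2 difference of -0.06. The array annotation does not say which probe sets lie in the deleted part of the gene.

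**Figure D1:**
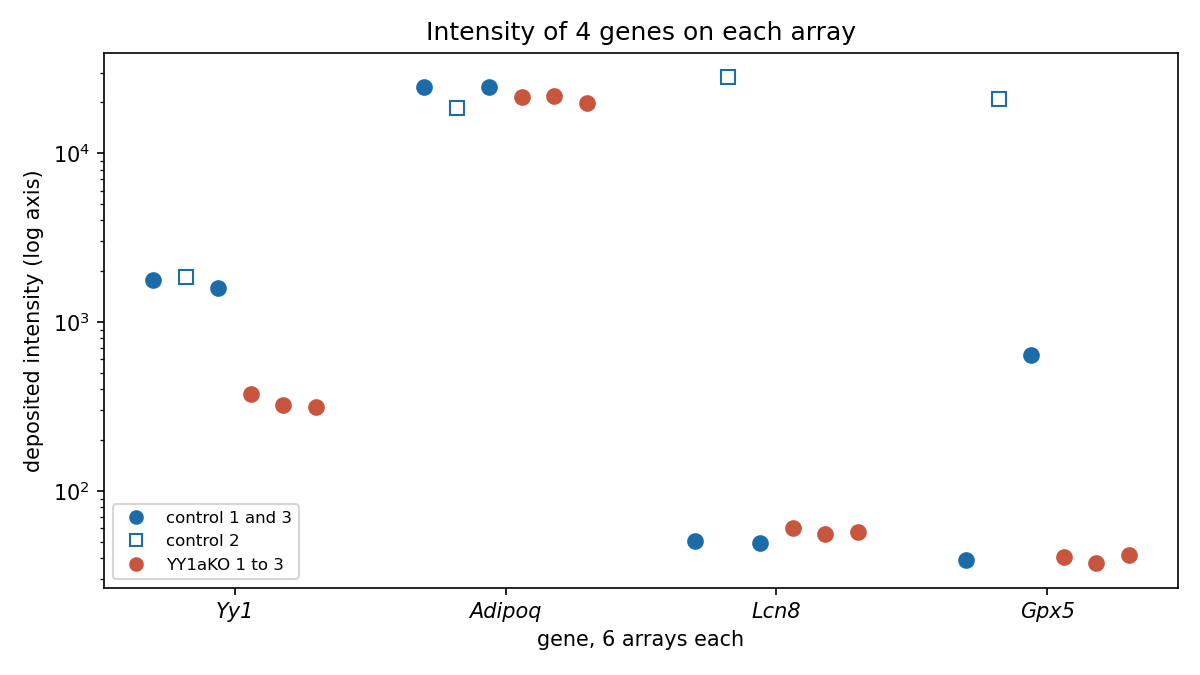
Deposited intensity (log axis) of Yy1, Adipoq, Lcn8 and Gpx5 on each of the 6 arrays, with 1 point per array. Yy1 lies at 315 to 373 in YY1aKO and at 1596 to 1846 in controls, while Lcn8 is near 50 on 5 arrays and at 28166 in control 2.

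The question set by the design is how loss of Yy1 in adipocytes changes gene expression in the fat of cold-exposed mice. As the groups also differ in the Cre transgene, an effect of Cre cannot be told apart from one of Yy1 loss. On the mixed background, strain alleles may differ between the groups too. The largest rise was in Ubd, which encodes a ubiquitin-like protein induced by inflammatory cytokines. It read 205, 77.5 and 100.5 in controls and 5696, 5231 and 4300.1 in YY1aKO, a log2 fold change of 5.43 ± 0.37 (SE). Orm2, an acute-phase plasma protein, rose by 4.01 ± 0.16, and Ly6h by 3.55 ± 0.34. Acta1, the skeletal muscle actin, rose by 3.43 ± 0.30, and Trib3, a pseudokinase induced by cell stress, by 3.07 ± 0.47 (2.15 without _s_at and _x_at probe sets). Wfdc12 (2.92), Dct (2.78), Cidea (2.68), Cxcl10 (2.48) and Gsdme (2.36, or 0.88 with the mean of its probe sets) completed the 10 genes with the largest rises among the genes tested, which leave out those below the filter. The largest fall was in Nnat, an imprinted gene, which went from 3625, 1238 and 2880 in controls to 149, 51.9 and 33.7 in YY1aKO, a log2 fold change of -5.20 ± 0.65 (-5.81 without YY1aKO 1). The imprinted gene Peg3 had -3.65 ± 0.39. Cyp2e1, a cytochrome P450 of very high intensity in controls (8647 to 19747), had a log2 fold change of -4.29 ± 0.64 (-4.97 without YY1aKO 3). Chdh, the choline dehydrogenase of mitochondria, had -3.44 ± 0.18, Eci3 -3.82 (-4.54 without control 2), Ces1f -3.29 and D430019H16Rik -3.73. Calml3 (-4.54), Gstm7 (-3.74) and Zfp185 (-3.30, or -2.42 and an adjusted p of 0.078 with the mean of its probe sets) also fell, and their control levels were highest in control 2, where Calml3 read 2623 against 187 in control 1 and 1650 in control 3. The 3 genes had -3.79, -2.81 and -2.36 without control 2, and without control 1 -5.70, -4.75 and -4.00. All 3 lost their call without control 3 and without each YY1aKO array (Calml3 adjusted p = 0.075 without YY1aKO 1). Nnat lost its call without YY1aKO 2 or YY1aKO 3, and Cyp2e1 without control 3, YY1aKO 1 or YY1aKO 2. Detection calls were not used here, so how much of a low reading is background is not known. Orm2 (24.2 to 34.5), Wfdc12 (33.9 to 71.2) and Dct (37.7 to 85.1) read low in controls. Calml3 (19.6 to 96.9), Eci3 (28.7 to 34.1), Gstm7 (29.6 to 47.7), Nnat (33.7 to 149) and D430019H16Rik (42.2 to 45.3) read low in YY1aKO. Their fold changes may be understated for this reason. For Calml3 and Gstm7, the high readings in controls 2 and 3 (Gstm7 119, 1762 and 551 in controls 1 to 3) may instead overstate the fall. The order of the largest changes, that of Nnat included, is not exact.

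In all, 1538 of the 7436 genes changed at an adjusted p under 0.05 in limma, 958 higher and 580 lower in YY1aKO. Of these, 173 rose and 177 fell by at least 2-fold, and all 1538 had their 3 YY1aKO values outside the control range. Over all genes tested, the groups did not overlap for 3529 (47.5%), where chance gives 10%. Without control 2 the count was 3353 (1893 higher, 1460 lower), and it held all 1538 genes in the same direction. The count fell to 394 without control 3, 253 without YY1aKO 1, 33 without YY1aKO 2 and 24 without YY1aKO 3, and of the 88 named genes that passed with all 6 arrays, only Yy1, Ubd, Orm2, Chdh and Tpi1 passed in each of these fits and in those without control 1 and control 2. With control 2 and 1 further array left out, 2318 to 2741 genes passed.

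Of 17 tested genes of cholesterol synthesis, 7 were higher over all genes tested and none was lower (8 higher when adjusted over the list alone), and the median log2 fold change was 1.21. The list passed camera with a preset correlation (adjusted p = 0.0088), but not with an estimated correlation (adjusted p = 0.993), with fry (adjusted p = 0.18) or among the brightest 40% of genes (adjusted p = 0.11). Pmvk, a kinase of the mevalonate pathway, rose by 1.87 ± 0.25 and the isomerase Idi1 by 1.73 ± 0.42. Sc5d (1.42 ± 0.21) and Hsd17b7 (1.33 ± 0.25), enzymes of late sterol synthesis, also rose. Without control 2, which lay above the other controls by a median of 0.96 log2 units in this list, 15 members were higher, the median was 1.60 and the adjusted p was 7.7e-06 with the preset and 0.859 with an estimated correlation. By fry the list passed without control 2 (adjusted p = 0.038). With each other array left out the adjusted p stayed between 0.0013 and 0.045 with the preset correlation, and was 0.899 or more with an estimated correlation.

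Fatty acid synthesis had 2 of 20 tested members higher (1 adjusted over the list alone) and none lower, with a median of 0.65 and an adjusted p of 0.13. Fasn, the fatty acid synthase, rose by 1.77 ± 0.33 and the elongase Elovl5 by 0.68 ± 0.17. The list passed without control 2 (10 higher, none lower, adjusted p = 0.031, or 0.859 with an estimated correlation) and without YY1aKO 1 (adjusted p = 0.018, or 0.999 with an estimated correlation). It also passed with every probe set on its own (adjusted p = 0.0032), no filter (0.036) or the replicate block (0.036), but not with an estimated correlation (adjusted p = 0.993, 0.990 and 0.978 in turn). Its median lay 0.77 log2 units below the other controls in control 2. In glucose uptake and glycolysis, 5 of 17 members were higher and 2 lower, by either adjustment. Gpd1, which makes glycerol 3-phosphate for triglycerides, rose by 2.23 ± 0.39 (1.27 with the mean of its probe sets). Pkm rose by 1.41 and Aldoa by 1.28, while Tpi1, the triose phosphate isomerase, had a log2 fold change of -1.75 ± 0.13. The list did not pass (adjusted p = 0.47), nor without control 2 (8 higher, 4 lower, adjusted p = 0.32).

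Thermogenic genes did not move as a group. Of 11 tested members 2 were higher, 1 was lower and 8 did not pass, by either adjustment, with a median of 0.22 and an adjusted p of 0.90. Cidea, a lipid-droplet protein abundant in brown fat, read 199.8, 63.8 and 99.4 in controls and 580, 676 and 845 in YY1aKO. Cox7a1 rose by 1.05 ± 0.18, and Plin5, a lipid-droplet protein of oxidative tissues, had -1.35 ± 0.26. Cox8b differed by 0.22 ± 0.66, or by -0.46 without control 2, and passed in neither fit. Other marker genes lay below the intensity filter and were tested only in the fit with no filter. There Ucp1, the uncoupling protein of brown fat, read 23.8 to 25.5 in controls and 118, 67.6 and 306 in YY1aKO (log2 fold change 2.45 ± 0.53, adjusted p = 0.041). Ppargc1a, a coactivator of mitochondrial genes, read 134.5 to 242.5 in controls and 15.3 to 35.0 in YY1aKO (-2.93 ± 0.36, adjusted p = 0.012). Elovl3 (2.21 ± 0.80) and Dio2 (0.34 ± 0.13) did not pass. As Ucp1 read low in controls and Ppargc1a in YY1aKO, their fold changes may be understated. Without control 2 the thermogenic list had 3 members higher and 4 lower, a median of -0.46, and still did not pass (adjusted p = 0.66).

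**Figure D2:**
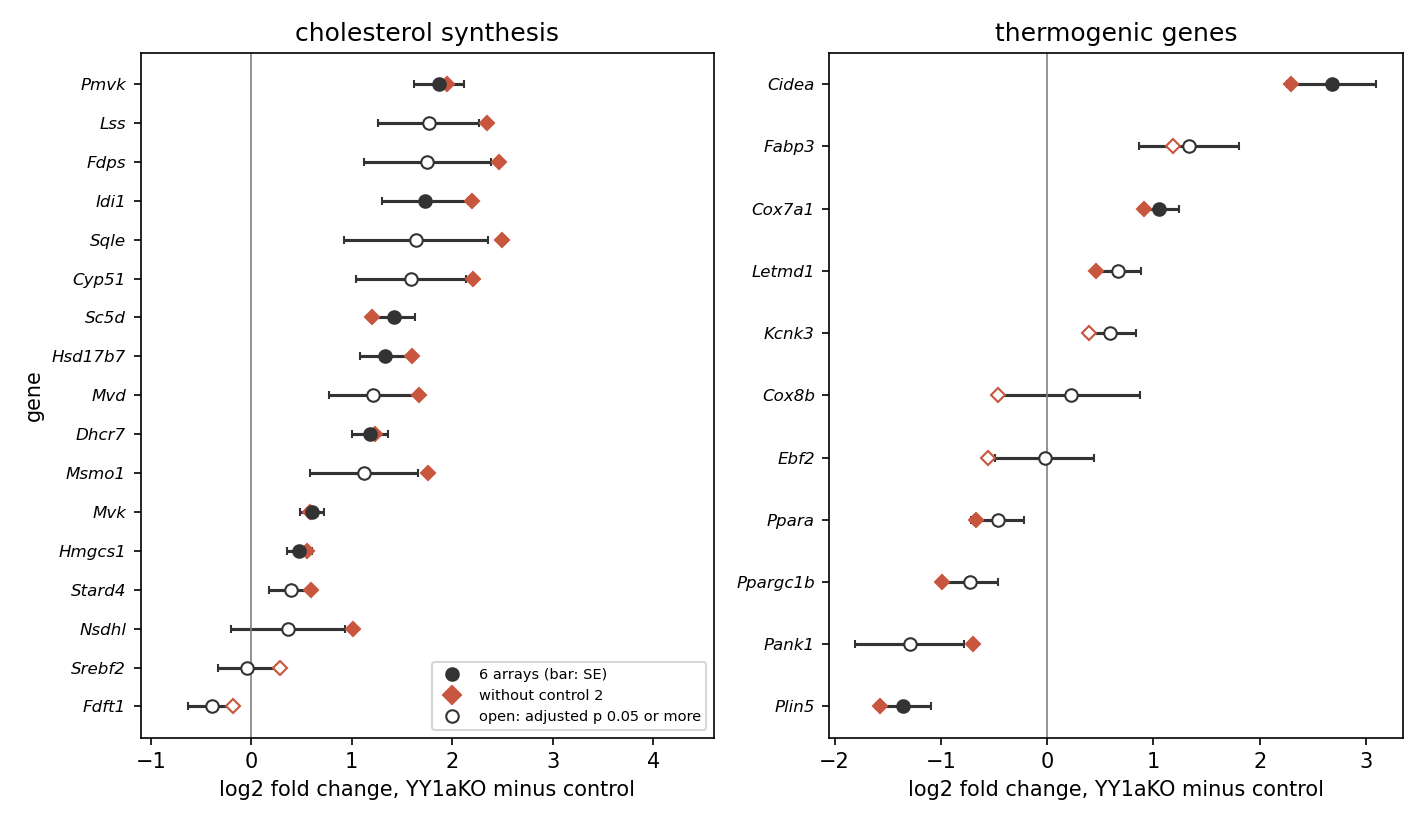
Log2 fold changes (YY1aKO minus control) of the tested genes of the cholesterol synthesis and thermogenic lists. Circles give all 6 arrays with the standard error, diamonds the values without control 2, and filled symbols an adjusted p under 0.05. In cholesterol synthesis 7 genes passed with 6 arrays and 15 without control 2, all higher, while the thermogenic genes lie on both sides of 0.

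Nuclear-encoded subunits of oxidative phosphorylation moved both ways, with 3 of 44 higher and 5 lower (6 and 5 adjusted over the list alone) and a median of -0.04 (adjusted p = 0.66). Without control 2 the counts were 8 higher and 17 lower, with a median of -0.09 (adjusted p = 0.18). Uqcrq rose by 0.97 ± 0.14, while Ndufc1 had -0.87, Atp5a1 -0.74 and Cox7c -0.73. In mitochondrial biogenesis and translation 5 of 29 were higher and 1 lower, by either adjustment, led by Lonp1 (0.96), Mrps18b (0.89) and Mrpl16 (0.62), with Mrps35 at -0.59. The tricarboxylic acid cycle list had 1 of 17 lower, Suclg2 (-2.20 ± 0.29). Fatty acid oxidation had 1 of 22 higher, Acaa2 (0.68), and 1 lower, Ehhadh (-1.30), and both counts were alike adjusted over the list alone. The adjusted p of these lists was 0.63, 0.97 and 0.83 in turn. Without control 2 they had 7 higher and 5 lower, 2 and 4, and 1 and 4, and none passed (adjusted p = 0.87, 0.32 and 0.32).

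Mature white adipocyte genes did not move as a group. Of 23 tested members, by either adjustment, 2 were lower, Mest (-2.53 ± 0.53) and the corepressor Nrip1 (-1.09 ± 0.12), and none was higher (adjusted p = 0.97). Adipoq differed by -0.10 ± 0.14, Lep by 0.11 ± 0.41, Fabp4 by 0.13 ± 0.10 and Pparg by 0.64 ± 0.36, none past the threshold. In control 2 this list lay 1.13 log2 units below the other controls by its median, and without control 2 none was higher and 4 were lower (adjusted p = 0.32). In lipolysis and adrenergic signalling none of 13 passed, by either adjustment (adjusted p = 0.49), and Abhd5 (1.13) and Adcy3 (-0.64) came closest. Without control 2, 1 was higher and 1 lower (adjusted p = 0.58). None of 19 insulin and IGF signalling genes passed by either adjustment (adjusted p = 0.90), while without control 2, 1 was higher and 6 were lower, and the median went from 0.01 to -0.33 (adjusted p = 0.13).

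Among secreted proteins tied to energy expenditure, 1 of 14 rose and 1 fell (1 and 0 adjusted over the list alone, list adjusted p = 0.49). Angptl6, an angiopoietin-like hormone, read 74.2 to 99.2 in controls and 195 to 254.5 in YY1aKO (1.32 ± 0.16), and Rbp4, the retinol carrier, had -1.70 ± 0.45. Fgf21, a hormone induced by fasting and mitochondrial stress, lay below the filter and read 28.8 to 37.2 in controls and 96.6, 88.9 and 238 in YY1aKO (1.99 ± 0.39, adjusted p = 0.033 with no filter). With such low control readings the rise of Fgf21 may be understated. Nmb differed by 0.17 ± 0.27 and did not pass. Nucb2 differed by -0.23 ± 0.82 with all arrays, with 2907 in control 2 against 360.5 and 401 in the other controls. Without control 2 it was higher in YY1aKO by 0.75 (adjusted p = 0.018). Without control 2 the list had 3 higher and 6 lower (adjusted p = 0.18 by camera, and 0.048 by fry). Gdf15 was not analysed here.

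In the integrated stress response 4 of 21 were higher and 2 lower (5 and 2 adjusted over the list alone), with Atf3 at 1.41 ± 0.17, Atf5 at 1.34 ± 0.24 and Phgdh, of serine synthesis, at -1.19 ± 0.26. With the mean of its probe sets Phgdh had -0.45 and did not pass (adjusted p = 0.69). Without control 2, 10 of this list were higher and 3 lower. In p53 targets and senescence 5 of 15 were higher and none lower, by either adjustment, and 7 were higher and 3 lower without control 2. Cdkn1a, the cell-cycle inhibitor p21, read 234, 288 and 310 in controls and 879, 853 and 938 in YY1aKO (1.69 ± 0.13). Cdkn2b rose by 1.60, Zmat3 by 1.14 and Aen by 0.97. NRF2 targets and antioxidants had 2 higher and 4 lower of 21, by either adjustment, among them Gsta3 (-2.53 ± 0.40), the plasma peroxidase Gpx3 (-2.11 ± 0.23), Gsta4 (-1.19) and Srxn1 (1.24), and without control 2 the list had 3 higher and 6 lower. The endoplasmic reticulum chaperones had 1 of 21 higher, by either adjustment, the oxidase Ero1a (1.33 ± 0.25). These 4 lists had adjusted p values of 0.33, 0.34, 0.33 and 0.33 in turn, and the first 3 had 0.15, 0.47 and 0.28 without control 2. By fry, which does not compare a list with other genes, the p53 list had an adjusted p of 0.074, and 0.0054 without control 2. The chaperones lay 1.16 log2 units higher in control 2 than in the other controls by their median, and without control 2 this list passed with 13 members higher (adjusted p = 0.0013, or 0.859 with an estimated correlation). It also passed with array weights (adjusted p = 0.018, or 0.891 with an estimated correlation) and with the epididymis list as a covariate (adjusted p = 0.00029 with the preset correlation). Both settings bear mainly on control 2, so they are not checks separate from leaving it out.

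Interferon-induced genes had 5 of 23 higher and none lower by either adjustment, with a median of 0.40, and passed as a list (adjusted p = 0.029, or 0.993 with an estimated correlation). The call also ended without control 2 (adjusted p = 0.17), with the mean of probe sets (0.061), the brightest 40% of genes (0.30), array weights (0.099) and fry (0.24), and with the epididymis list as a covariate (adjusted p = 0.35, median 0.05). Cxcl10, a chemokine, read 40.6 to 67.7 in controls and 392, 177 and 416 in YY1aKO. Usp18 rose by 1.51 ± 0.22, Gbp3 by 1.51 ± 0.40 and Ifit1 by 1.48 ± 0.20. In control 2 the list lay 0.76 log2 units below the other controls by its median, and without that array the 5 higher members still passed while the median of the list went from 0.40 to 0.14. Macrophage markers did not pass in any of 22 tested genes, by either adjustment, and Adgre1, which encodes the marker F4/80, differed by 0.48 ± 0.28. Inflammatory cytokines and chemokines had 2 of 13 higher and 1 lower (3 and 1 adjusted over the list alone), Cxcl10 and Ccl8 (1.34) against Cxcl12 (-0.72), which had -0.28 with the mean of its probe sets (adjusted p = 0.39). The macrophage and cytokine lists had adjusted p values of 0.83 and 0.90. Without control 2 they had 1 higher and 2 lower, and 3 and 4 (adjusted p = 0.32 and 0.55).

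Of the stromal and vascular lists, extracellular matrix had 1 of 29 lower (0 adjusted over the list alone), Mmp14 (-0.79 ± 0.18, or -0.49 and an adjusted p of 0.089 with the mean of its probe sets), and Col1a1 differed by -0.20 ± 0.10 without passing. None of 20 adipose progenitor genes and none of 19 endothelial genes passed by either adjustment. Mesothelium and visceral fat had 1 of 16 lower (0 adjusted over the list alone), Tcf21 (-0.63 ± 0.14). The adjusted p of these 4 lists was 0.33, 0.31, 0.93 and 0.13 in turn. In control 2 the medians of these 4 lists lay 0.92, 1.00, 1.51 and 1.10 log2 units below the other controls in turn. Without control 2 all 4 passed in the lower direction, with 12, 11, 11 and 7 members lower and at most 1 higher, with medians of -0.30, -0.35, -0.44 and -0.55 and adjusted p values of 0.0028, 0.010, 0.0028 and 0.0034. The adjusted p with an estimated correlation was 0.859 for each. By fry without control 2, only the progenitor list of these passed (adjusted p = 0.048). The mesothelium list also passed without YY1aKO 1 (adjusted p = 0.038) and with every probe set on its own (0.043), and with array weights it passed together with extracellular matrix and progenitors (0.018, 0.018 and 0.042). With an estimated correlation the adjusted p was 0.999, 0.993 and 0.891 in these 3 settings. With the epididymis list as a covariate, added after seeing the data, all 4 lists passed in the lower direction with the preset correlation. Their adjusted p values were 0.00058, 0.0061, 0.00029 and 0.0040 in turn. Array weights gave control 2 a weight of 0.12, and this covariate stems mainly from that array. Neither is a check separate from leaving control 2 out. The endothelial list had a median of 0.04 with all arrays, although camera gave it the lower direction.

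**Figure D3:**
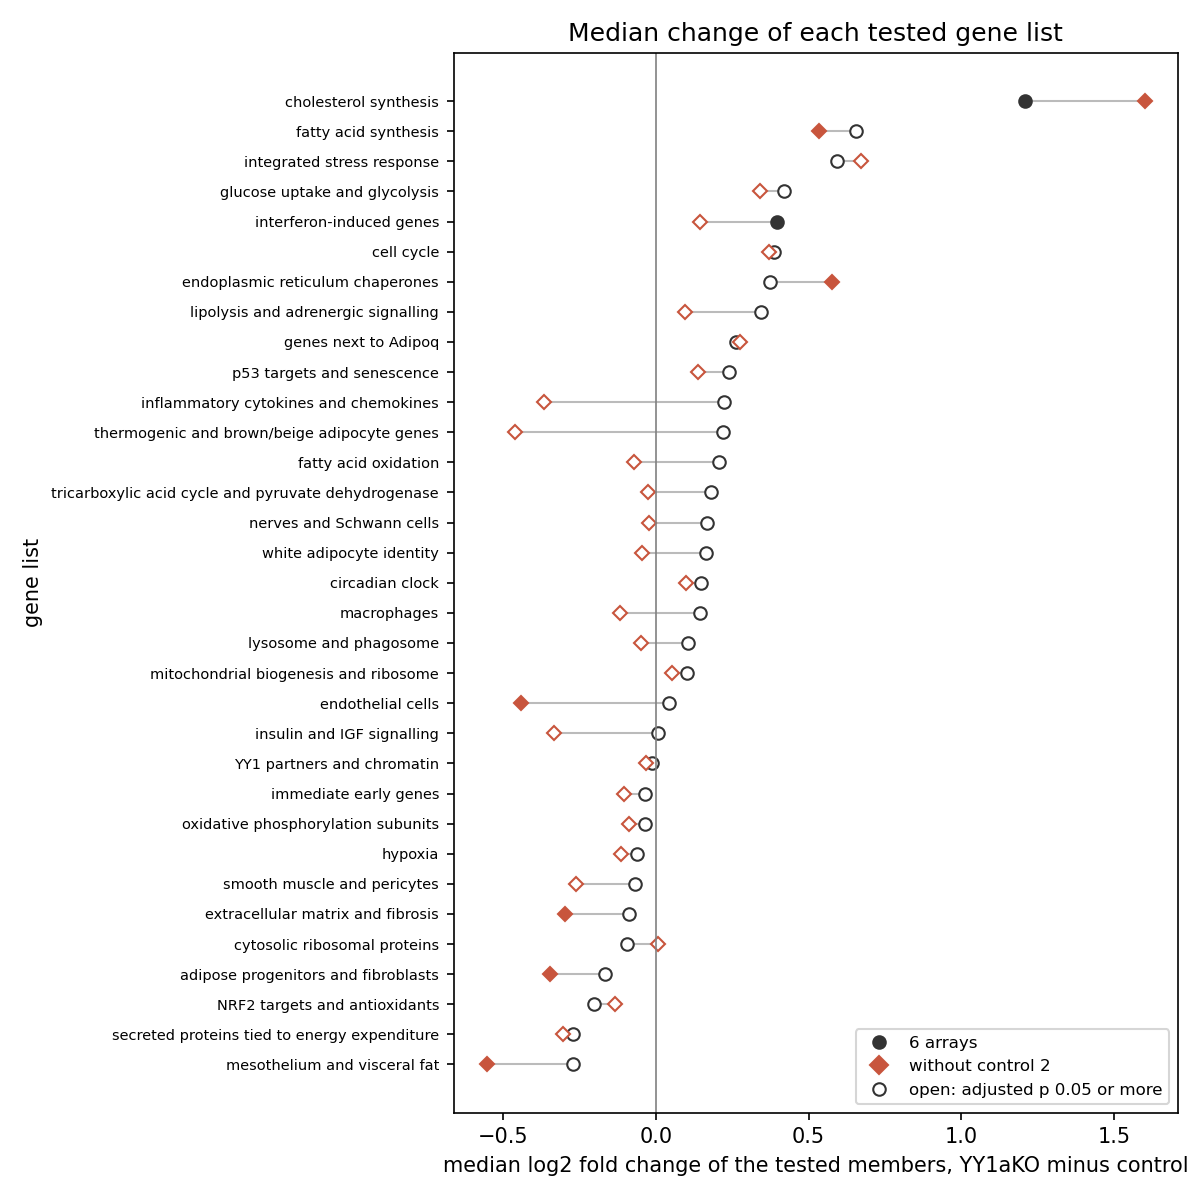
Median log2 fold change (YY1aKO minus control) of the tested members of each of the 33 gene lists tested, with all 6 arrays (circles) and without control 2 (diamonds), filled where the preset camera adjusted p was under 0.05. Cholesterol synthesis lies highest, at 1.21 with 6 arrays and 1.60 without control 2.

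Genes tied to YY1 itself included 1 of 21 higher, Ino80 (0.81 ± 0.13), the catalytic subunit of a remodelling complex that YY1 joins. Of the 4 lower ones, 1 was Yy1, and Ogt had -0.76 ± 0.14 and Ctcf -0.55 ± 0.12. The count was 2 higher and 4 lower adjusted over the list alone, and the list did not pass (adjusted p = 0.33), except with every probe set on its own (adjusted p = 0.010, or 0.993 with an estimated correlation). The list holds the deleted gene itself, and without Yy1 these adjusted p values were 0.58 and, with every probe set, 0.078. Without control 2, 2 were higher and 6 lower (adjusted p = 0.46). As a check of the samples, Eif2s3y of the Y chromosome read 556 to 1030 on all arrays and the X-inactivation transcript Xist 45.3 to 51.4. Uty of the Y chromosome was lower in YY1aKO (-0.74 ± 0.12, adjusted p = 0.014), while Kdm5d (-0.44) and Eif2s3y (0.19) did not pass.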

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

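The tests on control replicate 2 and the list of imprinted genes were chosen after the values were seen. A signal was present in data that the comparison does not use, the probe sets without a single gene name. Of 959 such probe sets over the filter level, 84 were higher in YY1aKO past the threshold and above every control array, and 78 were lower and below every control array. In the main comparison 958 of 7436 tested genes were higher and 580 lower, all outside the control range, so such changes were not particular to these probe sets. The most strongly raised of them read 29.7 to 199.3 in controls and 436 to 611 in YY1aKO, and the most strongly lowered 622 to 1014 and 84.6 to 134.1.

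Control replicate 2 stands apart from the other 5 arrays. A mislabelled knockout sample is argued against by Yy1, which lay 2.31 log2 units above the highest YY1aKO array. Epididymal tissue in this sample is a candidate explanation: the epididymis and testis list, fixed before the data were examined, had 14 members on the array, a median excess of 4.62 log2 units over controls 1 and 3 (the 95th percentile of 10000 random lists of matched level was 0.12), and 7 members above 1000. The most abundant were Lcn8 (28166), Gpx5 (21047), Lcn5 (17737) and Adam7 (14079), which read at most 75.5 on the other arrays, apart from Gpx5 in control 3 (639). No member of the list read above 106.8 in control 1 or YY1aKO. No biological explanation was tested, since the design names none that would set 1 control apart.

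Some genes that fell in YY1aKO were raised in control 2, 17 of the 580 by over 2-fold, among them Calml3, Gstm7 and Zfp185, and 20 of the 958 that rose were over 2-fold lower in control 2. Whether epididymal tissue in control 3 also lies behind such falls cannot be told apart from an effect of Yy1 loss, as the test on controls 1 and 3 gave a split answer. Gpx5 differed by -1.99 log2 units between YY1aKO and the mean of controls 1 and 3, which came from control 3 alone (0.03 against control 1), while Lcn8 differed by 0.20. In control 1, Gpx5 read 39.0 and Prm1 91.3, against at most 41.5 and 106.8 in YY1aKO, so these genes gave no sign of such tissue there. Control 3 (Gpx5 639, Prm1 510) remains in the fits without control 2. Another test, on genes chosen across the array, was dropped in 2 versions because YY1aKO values entered the choice of genes.

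The imprinted genes Nnat, Peg3 and Mest fell in YY1aKO. Epididymal tissue in control 2 is argued against as the cause, since the 3 genes read lower in that array than in controls 1 and 3. These differences were -1.38, -1.12 and -1.18 log2 units in turn. Leaving control 2 out could thus only deepen their falls, so that fit was no separate test. In it all 3 kept an adjusted p under 0.05 in limma, and their log2 fold changes moved by -0.46 at most, away from 0. A fall of imprinted genes in general is argued against too. The other 22 tested genes of a list of 52 imprinted genes had a camera p of 0.696 with the preset correlation and a median log2 fold change of -0.0037, with Ndn (1.38, chosen after its value was seen) higher and Cd81 (-0.64, likewise) lower. An effect of Yy1 loss on these 3 genes, or on the cells that express them, stays open and was not tested.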

How the results depend on the processing

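Yy1 kept its fall and its call in all 17 alternatives run for it (log2 fold change -2.45 to -2.33, or -1.17 for the mean of its probe sets). The thermogenic list passed in none of the settings in which it was tested. With the brightest 40% of genes it had too few members for a test. The count of changed genes (1538) moved by under 1.5 times with the mean of probe sets, without _s_at and _x_at probe sets, with either other filter, either scaling, a trend with a robust prior, and, added after seeing the data, without control 2 at a fold of at least 1.5 (1143 to 1520 over these). The median change of all genes was 0.06, 0.06 and 0.04 with the deposited and the 2 other scalings. The count was 2424 probe sets (1535 higher, 889 lower) with every probe set on its own, 2628 (1543, 1085) with array weights, which gave control 2 a weight of 0.12, 2347 (926 lower) at an adjusted p under 0.10, 991 (580 higher) at a fold of at least 1.5, 166 (108, 58) with an unequal-variance test, and 3173 (1704, 1469) with the epididymis list as a covariate, added after seeing the data. With 1 array left out it ran from 24 (8 higher, 16 lower, without YY1aKO 3) to 3353 (1893, 1460, without control 2), and 21 of the 1538 genes passed in all 6 such fits. With control 2 and 1 further array left out, added after seeing the data, it ran from 2318 to 2741, where leaving out a further control leaves 1 control, assumed to vary like the others. With the replicate block it was 54 (22, 32), and 72 named genes lost a call while 52, passing before or not, did not change. Same-numbered samples did not deviate together (correlations -0.14, -0.12 and -0.12), and not every sample correlated best with its own number. Nothing shows that the numbers pair the samples, but this check cannot exclude it. With 3 arrays per group, the deviations of controls 1 and 3 largely mirror that of control 2 (correlations -0.91 and -0.79). The count of lists past (2) was 1 with the mean of probe sets, 5 with every probe set, 4 with no filter, 0 with the brightest 40% of genes, 5 with array weights, 6 with the covariate, 0 with an estimated correlation and 0 with fry (lowest fry adjusted p 0.074, but 6 lists past with fry without control 2), 3 with the block, and 2 to 7 with 1 array left out. The 6 lists past with fry without control 2 were cholesterol synthesis, p53 targets, secreted proteins, adipose progenitors, nerves and genes next to Adipoq. Nucb2 (-0.23) turned to 1.02 with the covariate and ran from -0.75 without control 1 to 0.75 without control 2. No list passed with an estimated correlation in the fits with every probe set, no filter, array weights, the block or 1 array left out either, which was added after seeing the data (lowest adjusted p 0.859). An estimated correlation was not run with the covariate. Of the other values of named genes, 373 lost and 37 gained a call and 1639 did neither. The cause of the changed calls was not tested. Fewer samples alone do not account for the falls to 24 to 394 genes without control 3 or 1 YY1aKO array, in fits that kept control 2. With control 2 and 1 YY1aKO array left out, so with fewer arrays still, 2436 to 2741 genes passed. Genes near background, such as Ucp1 and Elovl3, are limited by signal over background.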

Other observations

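Further lists fixed before the data were examined gave few calls. Of 8 tested cell cycle genes 2 were higher and none lower, by either adjustment, Ube2c (0.95 ± 0.24) and Cdc20 (0.87 ± 0.16), with a list adjusted p of 0.33. Without control 2, 3 were higher (list adjusted p = 0.32), and the list passed with no filter (adjusted p = 0.045, or 0.990 with an estimated correlation). Immediate early genes had 2 of 20 higher and 1 lower, by either adjustment, Ccn1 (1.58 ± 0.28, or 0.99 and an adjusted p of 0.098 without _s_at and _x_at probe sets) and Atf3 against Egr1 (-0.89 ± 0.21). Hypoxia genes had 1 of 13 higher and 3 lower (1 and 4 adjusted over the list alone), Ero1a against Ndrg1 (-1.13 ± 0.19), the glucose transporter Slc2a1 (-0.87 ± 0.18) and Mxi1 (-0.79, or -0.52 and an adjusted p of 0.072 with the mean of its probe sets). In lysosome and phagosome 2 of 20 rose, the calcium channel Mcoln1 (1.10 ± 0.16) and the cholesterol exporter Npc1 (0.87 ± 0.11), and 2 fell, Ctsl (-0.77) and Atp6v1b2 (-0.53, or -0.33 and an adjusted p of 0.058 with the mean of its probe sets), by either adjustment. Of 14 clock genes 1 rose, Clock (0.86 ± 0.13), and of 11 smooth muscle genes 1 fell, Myh11 (-0.91 ± 0.12), by either adjustment. Rps19 (-0.47) was the single gene of 21 cytosolic ribosomal proteins past the threshold (0 adjusted over the list alone). The adjusted p of these lists was 0.79, 0.47, 0.97, 0.64, 0.33 and 0.13 in turn, and the ribosomal list passed without control 1 (adjusted p = 0.0047, or 0.899 with an estimated correlation). Without control 2 the 6 lists had 3 higher and 4 lower, 3 and 6, 5 and 5, 1 and 1, 0 and 2, and 1 and 2, and none passed as a list. None of 5 nerve genes passed by either adjustment (list adjusted p 0.90), and 1 was lower without control 2, where the list passed by fry (adjusted p = 0.048).

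Markers of other cells were mostly too few above the filter for a list test. Acta1 rose while the muscle tropomyosin Tpm2 had -0.68 ± 0.10, and the other 2 tested skeletal muscle genes did not pass (1 higher and 2 lower adjusted over the list alone, and 1 and 1 without control 2). No tested marker of T and NK cells (3), B cells (2), granulocytes (3), erythrocytes (3), or of mammary and skin epithelium (2) passed over all genes tested. Adjusted over the list alone, the 2 of mammary and skin epithelium were lower and none of the others passed. Without control 2, 1 of each was lower, apart from B cells (0). Of these 2, Epcam read 4247 in control 2 and 1287 in control 3 against 138 in control 1 and at most 100.5 in YY1aKO. Lcn2 of the granulocyte list read 11582 in control 2. The mesothelial marker Upk3b read 1098 to 3055 over the 6 arrays and Wt1 73.9 to 224.2. The subcutaneous or brown depot genes Tbx15, Shox2, En1, Zic1 and Lhx8 lay between 7.2 and 16.4 on all arrays, near background, and Hoxc9 rose (0.75 ± 0.16) by either adjustment. Without control 2, 1 of the 4 tested depot genes was higher and 1 lower. Epididymal and testis transcripts in control 2 (Lcn8 28166, Gpx5 21047) and control 3 (Gpx5 639, Prm1 510) go with the epididymal label, but were not raised in control 1 or YY1aKO. Upk3b and Msln (242.7 to 693), of the list of mesothelium and visceral fat, go with the visceral label on all 6 arrays. Tbx20 of the same list read 16.8 to 19.7 and does not go with it. The low readings of Tbx15 and Shox2 do not go with the subcutaneous label, while Hoxc9 of the same list read 156.3 to 362. As that list also holds brown depot genes, the low readings of En1, Zic1 and Lhx8 are not counted against this label. Leaving Tbx20 and Hoxc9 aside, these few genes lean to visceral fat. With no array of another depot to set them against, they do not settle the depot. Depot genes other than Hoxc9 were chosen after their values were seen.

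Rfc4, which neighbours Adipoq, rose in YY1aKO (1.51 ± 0.13, adjusted p = 0.0064). A candidate explanation is that the Adiponectin-Cre transgene carries extra copies of genes near its promoter. In the test set before its result was seen, Eif4a2, which lies beside Rfc4, differed by 0.26 ± 0.10 and did not pass (adjusted p = 0.12). The 3 tested neighbours within 100 kb (Eif4a2, Rfc4 and St6gal1) had a median of 0.26 against 0.37 for Dnajb11, the single tested gene farther away. St6gal1 (-2.05 ± 1.18) was raised in control 2. Without control 2 it had -0.62 (adjusted p = 0.011), Dnajb11 0.71 (0.0030), Eif4a2 0.28 (0.065) and Rfc4 1.63 (0.0005). With 1 gene in the comparison, extra copies and an effect of Yy1 loss cannot be told apart. The list of these genes, Adipoq included, had a camera adjusted p of 0.63, and 0.52 without control 2. By fry, which does not compare a list with other genes, it had 0.081, and 0.016 without control 2. Of the neighbours below the filter, Kng1, Hrg, Fetub, Ahsg, Masp1 and Crygs differed by -0.76 to 0.31 without passing. Without control 2 Masp1 had -0.61 and passed in limma with no filter (adjusted p = 0.016). Fetub went from -0.76 to 0.10 there, and neither it nor the other genes passed.

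The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 1538 genes in limma and was the 1 split with as many. The highest of the others gave 0, with 9 to 391 genes at an unadjusted p under 0.05, against 2772 for the real split.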
